A study of Homo sapiens with 12 samples.

How the data were processed

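RNA was measured in 12 libraries of MCF7 cells in 4 groups of 3 (Control, LSD1 knockdown, WT rescue, E239K rescue), with groups taken from the labels. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, stable lines were selected with puromycin or G418, total RNA was taken with Trizol, and libraries were made from 1 µg of total RNA with a strand-specific kit. Whether the strand was used in counting is not stated. Per the submitters' processing notes, DESeq 1.10.1 was among the tools, with no role given. The aligner, genome build, annotation and replicate type are not given in the sources used here, so no coordinates are reported.

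The deposited tables hold per-gene values whose unit no label names. They were taken as FPKM made by the authors, since they are not whole numbers, are never negative and sum to between 123255 and 145662 per library. All 12 tables list the same genes in the same order: 6307 Ensembl genes, of which 6290 (99.7%) got a symbol from GENCODE release 29, and 1173 newly assembled loci. The 5 reference genes looked up (ACTB, TBP, EEF1A1, RPLP0 and MALAT1) have no entry. In all, 7255 listed genes (97.0%) have at least a 2-fold ratio of group mean FPKM in 1 or more comparisons, and 6841 (91.5%) in WT rescue against knockdown. The tables are therefore a selected part of each library, and the percentages of genes called, the set tests and the scaling alternatives apply to that part. The lowest values showed no read steps (41 distinct ratios among 41 low values), so counts and depth are unknown and no counting interval can be given.

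The design was written before the data were examined, for read counts with a stated fallback for normalised values, and the fallback was used. Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in 3 or more libraries were kept: 6355 were tested (5529 Ensembl genes and 826 loci) and 1125 were not. The empirical Bayes test of limma 3.58.1 (trend and robust options, statmod 1.5.0, R 4.3.3) was fitted once to all 12 libraries with 1 mean per group (8 residual degrees of freedom), and the 6 pairs of groups were tested two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05. No further scaling was applied. A reversed gene is one called in knockdown against control and called in the opposite direction in a rescue against knockdown. Observed numbers were set beside the product of the call rates and 20 simulated draws of unchanged groups.

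The 26 gene lists were fixed before the data were examined, from general knowledge, and none was chosen on these samples. They cover the LSD1 and CoREST complex, NuRD, estrogen-induced genes, luminal identity, epithelial adhesion, mesenchymal, basal, matrix and invasion, G2/M, DNA replication, p53, interferon, NF-kB, TGF-beta, hypoxia, cholesterol, amino acid and endoplasmic reticulum stress, REST-repressed neuronal, HLA, fibroblast, immune, endothelial, ribosomal protein, mitochondrially encoded, histone and nuclear long noncoding RNA genes. The long noncoding RNA list had 0 members tested and the immune list 1. The other 24 were tested with camera (inter-gene correlation 0.01) on lists of at least 3 genes, adjusted over lists within a comparison. With an estimated correlation, camera kept the luminal calls in knockdown against control, both rescues against knockdown and between the rescues, and the adhesion calls in those comparisons and in WT rescue against control. All other set calls were lost with it. Calls adjusted over each list alone equal the printed member counts except where stated, for the lists described.

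Named genes followed a rule fixed before the data were examined: KDM1A and ESR1; the 10 largest rises and 10 largest falls (the first 5 in the 4 comparisons other than knockdown against control and E239K against WT rescue) among called genes with a mean of at least 5 and no overlap between the libraries of the 2 groups; and up to 4 members of each list with the smallest p. The mean of at least 5 was set for scaled counts and applied in FPKM. Among all tested genes, the libraries of the 2 groups did not overlap for 92.6% in knockdown against control and 85.5% in E239K against WT rescue, where chance gives 10% and the tables were selected for change. VIM, CASP3, FGB, AGR2 and SAT1 were chosen after their values were seen. Exon overlaps came from GENCODE: 30 of 232 named genes share exon bases with another gene on the same strand and 69 on the opposite strand. Those on the same strand include TAP2, ASNS, CD68 and TGFB2 (2064, 1985, 1789 and 1371 bases). Their FPKM cannot be assigned to them alone in any comparison.

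The fit was tested on simulated data: with 50 genes seeded at each fold, 70% were called at 1.5-fold, 94% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 3 false calls (1.63% of calls). camera called 20 of 20 seeded lists of 15 genes at 1.5-fold and 0 of 20 unseeded ones. Genes were simulated independently of each other and most were left unmoved, whereas most measured genes were called. The 0 therefore does not measure false list calls in these data. Settings varied as set beforehand were median-of-ratios scaling, upper-quartile scaling, no filter, a pseudocount of 0.1 with no filter, only the 6 libraries compared, replicate number as a block, an added 2-fold threshold, each library left out, camera with an estimated correlation, and fry. Count-based alternatives (the DESeq2 test and count filters) could not be run without counts. A pseudocount of 0.1 with the same filter, a filter of 5 FPKM and Ensembl genes only were added after seeing the data. So were both scalings for the reversal by direction, for genes changed in opposite directions by the rescues, for genes outside the other groups and for the mixture shares, the complex list without KDM1A, and simulated rescues with the control means, also as the reference for genes changed in the same direction by knockdown and by E239K against wild type. Replicate numbers did not pair the libraries: after removal of group means, correlations of same-number libraries ran from -0.17 to 0.18, and in 0 of 6 comparisons did all 3 pass 0.1. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.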

Results

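RNA sequencing was done on 12 libraries of MCF7 cells, a luminal breast cancer line that expresses estrogen receptor alpha. The libraries made 4 groups of 3. Control cells were compared with cells carrying a stable short hairpin RNA against LSD1 (LSD1 knockdown) and with knockdown cells given back either wild-type LSD1 (WT rescue) or LSD1 with the E239K amino acid change (E239K rescue). LSD1, encoded by KDM1A, is a histone demethylase found in the CoREST and NuRD complexes. The labels place the study's question in how the E239K form affects migration, invasion and estrogen receptor alpha levels in luminal cells.

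Each deposited table listed the same genes in FPKM, and 6355 genes passed the expression filter. The tables hold a selected part of each library: 7255 of the listed genes (97.0%) differed at least 2-fold in mean FPKM in 1 or more of the 6 comparisons of groups. Shares of changed genes therefore describe this selection, not the transcriptome. The listed FPKM summed to between 123255 and 145662 per library, and read totals were not given, so the depth is unknown. Across the listed genes, replicates of a group correlated at r = 0.986 to 0.993 (genes are not independent replicates). The median r was 0.815 between control and knockdown libraries and 0.601 between knockdown and WT rescue libraries. For E239K rescue libraries it was 0.940 with control, 0.900 with knockdown and 0.806 with WT rescue libraries. Between WT rescue and control libraries it was 0.906, so the E239K rescue correlated more with control than the WT rescue did. Group values are means ± SD in FPKM (n = 3), fold ratios are ratios of those means, and each log2 fold change is from log2(FPKM + 1), followed by its SE. Counts of called genes past 2-fold or 1.5-fold, and shares within 1.5-fold of a weighted mean, also use log2(FPKM + 1). That scale understates changes of genes near or under 1 FPKM, so such genes pass a fold bound less often than by ratios of means. Nothing in the labels says whether the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples.

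KDM1A (ENSG00000004487), the gene targeted, stood at 37.9, 37.7 and 38.6 FPKM in the control libraries and at 7.18, 6.65 and 7.54 FPKM in the knockdown libraries. It stood at 253, 262 and 214 FPKM in the WT rescue libraries and at 235, 285 and 281 FPKM in the E239K rescue libraries. The knockdown mean was 5.34-fold under control (log2 fold change -2.27, SE 0.09, adjusted p = 9.5e-10). KDM1A in the WT rescue was 6.38-fold above control (log2 fold change 2.64, SE 0.09, adjusted p = 1.2e-09), and in the E239K rescue 7.01-fold above control (log2 fold change 2.77, SE 0.09, adjusted p = 2.6e-09). Between the rescues, KDM1A was not past the threshold (log2 fold change 0.14, SE 0.09, adjusted p = 0.189), although without E239K rescue replicate 1 it was (0.22, adjusted p = 0.0383). These values sum the endogenous and the introduced copy, and gene-level FPKM cannot separate the forms.

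**Figure D1:**
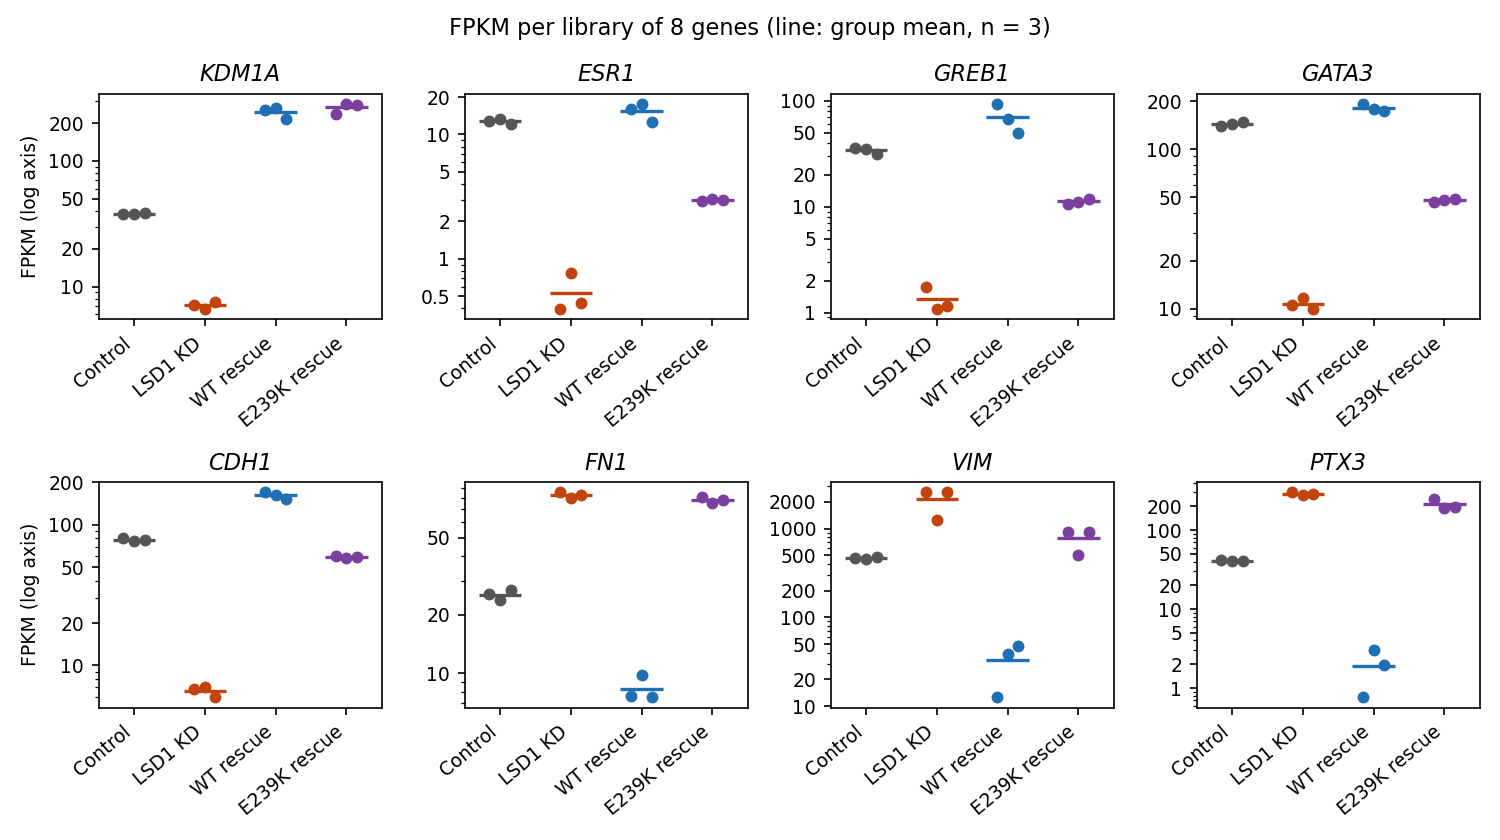
FPKM of 8 genes in each of the 12 libraries (log axis), with 1 point per library and a line at each group mean (n = 3). ESR1, GREB1, GATA3 and CDH1 were lowest in the knockdown libraries, and FN1, VIM and PTX3 were lowest in the WT rescue libraries.

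The first question was how the LSD1 knockdown cells differed from control cells. Here and below, the values are differences between groups, and whether LSD1 itself caused them was not tested. All luminal and most estrogen-induced genes tested were lower in the knockdown. ESR1 (ENSG00000091831), which encodes estrogen receptor alpha, fell from 12.8 ± 0.655 to 0.535 ± 0.203 FPKM, a 23.8-fold drop (log2 fold change -3.17, SE 0.12, adjusted p = 5.1e-10). GATA3, a luminal transcription factor, fell from 144 ± 4.64 to 10.8 ± 0.869 FPKM (log2 fold change -3.63, SE 0.07, adjusted p = 7.9e-12). Keratin 19 (KRT19) fell from 1487 ± 79.6 to 101 ± 2.91 FPKM (log2 fold change -3.87, SE 0.09, adjusted p = 2.2e-11). Of 19 luminal identity genes tested, 19 fell and 0 rose (median log2 fold change -2.92, camera adjusted p = 2.7e-06, adjusted p = 0.0327 with an estimated correlation). FOXA1, a pioneer factor for estrogen receptor binding, fell 8.54-fold, and SPDEF fell 10.1-fold. Among 32 estrogen-induced genes, 28 fell and 4 rose (median log2 fold change -1.79, camera adjusted p = 5.3e-05, adjusted p = 0.225 with an estimated correlation). These included TFF1 (8.17-fold lower), RET (22.2-fold lower), TPD52L1 (19.5-fold lower) and STC2 (19.7-fold lower).

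Most epithelial adhesion genes tested fell as well. E-cadherin (CDH1), the main adherens junction protein of epithelia, fell from 78.0 ± 1.86 to 6.58 ± 0.567 FPKM (log2 fold change -3.38, SE 0.07, adjusted p = 1.4e-11). Of 18 epithelial adhesion genes, 17 fell and 1 rose (median log2 fold change -2.78, camera adjusted p = 7.6e-06, adjusted p = 0.0169 with an estimated correlation), among them the tight junction gene CLDN3 and the desmosome genes DSP and JUP (19-fold, 9.38-fold and 10.3-fold lower). Of 17 mesenchymal genes, 13 rose and 4 fell (median log2 fold change 1.19, camera adjusted p = 0.0449, adjusted p = 0.320 with an estimated correlation, and adjusted p = 0.0576 after median-of-ratios scaling). Fibronectin (FN1) rose from 25.4 ± 1.43 to 83.2 ± 2.61 FPKM, tenascin C (TNC) from 11.2 ± 0.608 to 76.7 ± 3.09 FPKM, and the repressor of E-cadherin SNAI2 from 2.68 ± 0.0491 to 7.40 ± 0.358 FPKM. S100A4, a motility-linked calcium binding protein, went the other way, from 39.5 ± 3.74 to 9.45 ± 0.318 FPKM (log2 fold change -1.95, SE 0.11, adjusted p = 9.7e-09). VIM, chosen for display after its values were seen, rose 4.62-fold (log2 fold change 2.13, SE 0.43, adjusted p = 5.6e-04). Its knockdown libraries stood at 2566, 1265 and 2562 FPKM.

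Matrix and invasion genes rose in 15 of 20 and fell in 4, with 1 not called (median log2 fold change 1.11, camera adjusted p = 0.0244, adjusted p = 0.304 with an estimated correlation). The urokinase receptor PLAUR rose 6.18-fold, COL12A1 rose 3.67-fold and the protease ADAMTS1 rose 3.54-fold, while the membrane protease MMP15 fell 5.21-fold. Of 10 basal epithelial markers, 8 rose and 2 fell (median log2 fold change 1.39, camera adjusted p = 0.0676, not past the threshold). LAMC2 rose 5.70-fold and CAV2 rose 2.43-fold, against falls of ITGB4 (1.90-fold) and CD109. Markers of other cell types had few tested members. CD68, the single immune marker tested, rose 4.15-fold. It shares 1789 exon bases with another gene on the same strand, so its FPKM cannot be assigned to CD68 alone. Of 4 endothelial markers, ROBO4 and ESAM rose (3.09-fold and 2.75-fold), TIE1 fell, and CDH5 was at 0.229 ± 0.0405 FPKM in control and 0.140 ± 0.10 FPKM in knockdown, not past the threshold (median log2 fold change 0.63, camera adjusted p = 0.619 for the list). Of 3 fibroblast markers, ACTA2 fell (log2 fold change -0.32, adjusted p = 0.0371; adjusted over the list alone, 0 were called).

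The DNA replication genes tested, and most of the hypoxia and antigen presentation genes, rose in the knockdown. All 7 tested DNA replication genes rose (median log2 fold change 1.04, camera adjusted p = 0.00812, adjusted p = 0.225 with an estimated correlation), including PCNA, the sliding clamp, from 129.8 ± 4.01 to 248 ± 4.10 FPKM, and the licensing factor CDC6 (2.31-fold). Of 8 G2/M genes, 6 rose, 0 fell and 2 were not called (median log2 fold change 0.58, camera adjusted p = 0.0599, and adjusted p = 0.0483 after median-of-ratios scaling), with UBE2C 1.88-fold and CDC20 1.57-fold higher. Of 14 hypoxia and glycolysis genes, 11 rose and 3 fell (median log2 fold change 1.24, camera adjusted p = 0.0308, adjusted p = 0.292 with an estimated correlation). Carbonic anhydrase 9 (CA9) rose 8.08-fold, STC1 7.89-fold and GAPDH 3.04-fold, whereas DDIT4, an inhibitor of mTOR signaling, fell 3.71-fold. Of 11 HLA class I and antigen presentation genes, 9 rose and 2 fell (median log2 fold change 1.15, camera adjusted p = 0.0244, adjusted p = 0.225 with an estimated correlation), with the immunoproteasome subunit PSMB8 5.18-fold and the transporter TAP2 2.12-fold higher.

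Most stress response genes tested fell. Of 15 p53 target genes, 12 fell, 2 rose and 1 was not called (median log2 fold change -1.25, camera adjusted p = 0.0460, adjusted p = 0.304 with an estimated correlation, and adjusted p = 0.0638 after median-of-ratios scaling). GDF15 fell from 45.7 ± 0.265 to 5.92 ± 0.448 FPKM and the antiproliferative gene BTG2 from 11 ± 0.161 to 0.731 ± 0.150 FPKM. Of 16 amino acid and endoplasmic reticulum stress genes, 13 fell, 2 rose and 1 was not called (median log2 fold change -1.05, camera adjusted p = 0.0308, adjusted p = 0.304 with an estimated correlation, and adjusted p = 0.0588 after median-of-ratios scaling). Asparagine synthetase (ASNS) fell 6.04-fold and CHAC1 fell 9.16-fold. The list named for the LSD1 and CoREST complex holds KDM1A, the target of the hairpin, and 8 of its 9 genes fell and 1 rose (median log2 fold change -1.21, camera adjusted p = 0.0449, adjusted p = 0.304 with an estimated correlation). Without KDM1A, 7 of 8 fell and 1 rose, and the list was not past the threshold (median log2 fold change -1.11, camera adjusted p = 0.0746), with HMG20B 2.03-fold and ZNF217 2.39-fold lower. All 3 NuRD genes tested fell, CHD3 with the smallest p (log2 fold change -0.70, adjusted p = 3.4e-06; list median log2 fold change -0.70, camera adjusted p = 0.147).

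Signaling lists were mixed. Of 18 interferon-stimulated genes, 11 rose, 4 fell and 3 were not called (median log2 fold change 0.79, camera adjusted p = 0.0746), with IFI44 8.62-fold and IFIT3 4.60-fold higher and the tether BST2 6.73-fold lower. Of 16 TNF and NF-kB response genes, 10 rose, 5 fell and 1 was not called (median log2 fold change 0.59, camera adjusted p = 0.0911), FOSL1 rising 5.99-fold and JUNB falling 4.01-fold. Of 15 TGF-beta response genes, 11 fell, 3 rose and 1 was not called (median log2 fold change -1.03, camera adjusted p = 0.0911), among them the pseudoreceptor BAMBI (8.53-fold lower) and ID3 (3.03-fold lower). Of 9 cholesterol synthesis genes, 4 rose and 5 fell (median log2 fold change -0.36, camera adjusted p = 0.981). Of 13 neuronal genes repressed by REST, 4 rose, 7 fell and 2 were not called (median log2 fold change -0.61, camera adjusted p = 0.308), and L1CAM fell 8.50-fold. Few genes of 3 further lists were tested: 3 ribosomal protein genes, 3 mitochondrially encoded genes and 4 histone genes all fell (camera adjusted p = 0.139, 0.147 and 0.0911).

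Among single genes with the largest rises were TOMM6, part of the mitochondrial import channel (5.0 ± 0.686 to 206 ± 2.07 FPKM; log2 fold change 5.11, SE 0.15, adjusted p = 8.8e-11), the testis antigen MAGEB2 (1.41 ± 0.143 to 45.5 ± 1.18 FPKM; log2 fold change 4.27, SE 0.10, adjusted p = 1.8e-11), the protease inhibitor TFPI2 (13.3-fold), MYH15, FERMT3, SERPINB7, CALB2, TMEM158 and the pentraxin PTX3 (41.2 ± 0.929 to 289 ± 12.7 FPKM). The largest falls included IGFBP5, an insulin-like growth factor binding protein (197 ± 1.30 to 9.10 ± 0.490 FPKM; log2 fold change -4.29, SE 0.06, adjusted p = 1.5e-12), SPTSSB, CCN5, CLEC3A, YBX2, the estrogen target GREB1 (34.0 ± 2.04 to 1.33 ± 0.366 FPKM) and the chemokine CXCL12 (15.9 ± 1.5 to 0.141 ± 0.0347 FPKM). In all, limma called 5840 of 6355 genes, 2788 higher and 3052 lower. Of these, 2803 were also at least 2-fold on the log2(FPKM + 1) scale. The median log2 fold change was -0.16 and went to 0.02 with median-of-ratios scaling. TOMM6 shares 637 exon bases with another annotated gene on the same strand, so its FPKM cannot be assigned to TOMM6 alone.

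The next question was whether wild-type LSD1 restored expression. ESR1 rose from 0.535 ± 0.203 FPKM in the knockdown to 15.4 ± 2.56 FPKM in the WT rescue (log2 fold change 3.41, SE 0.12, adjusted p = 7.3e-11). All 19 luminal genes rose (median log2 fold change 3.41, camera adjusted p = 1.0e-05, adjusted p = 0.0430 with an estimated correlation), as did 28 of 32 estrogen-induced genes, with 2 lower and 2 not called (median log2 fold change 2.45, camera adjusted p = 2.0e-05, adjusted p = 0.285 with an estimated correlation), and 17 of 18 adhesion genes, with 1 lower (median log2 fold change 3.45, camera adjusted p = 2.0e-05, adjusted p = 0.0231 with an estimated correlation). CDH1 reached 162 ± 8.35 FPKM and TFF1 1354 ± 190.0 FPKM. Of 17 mesenchymal genes, 15 fell, 1 rose and 1 was not called (median log2 fold change -2.86, camera adjusted p = 0.00753, adjusted p = 0.289 with an estimated correlation), FN1 to 8.34 ± 1.30 FPKM and TNC to 1.28 ± 0.760 FPKM. Among markers of other cell types, CD68 fell 13.7-fold. Of 4 endothelial markers, ROBO4, ESAM and TIE1 fell (log2 fold changes -3.41, -3.22 and -0.70) and CDH5 was not called (median log2 fold change -1.96, camera adjusted p = 0.154, not past the threshold). Of 3 fibroblast markers, PDGFRB fell (-0.41), ACTA2 rose (1.42) and COL1A1 was not called (median log2 fold change 0.20, camera adjusted p = 0.802). The largest rises were CXCL12, NPY1R, GPNMB, IGFBP5 and TFF1 (log2 fold changes 5.41, 5.39, 5.18, 5.16 and 4.99, adjusted p at most 5.8e-11). The largest falls were AKR1B1, PTX3, LDHB, MT1E and FOSL1 (-6.77, -6.71, -6.57, -6.40 and -6.30, adjusted p at most 1.6e-09). limma called 6176 genes, 3099 higher and 3077 lower.

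Most luminal and adhesion genes in the E239K rescue stood between the knockdown and the WT rescue. ESR1 rose from 0.535 ± 0.203 to 2.97 ± 0.0737 FPKM (log2 fold change 1.38, SE 0.12, adjusted p = 9.5e-07), GATA3 to 47.7 ± 0.921 FPKM and CDH1 to 59.1 ± 0.737 FPKM. All 19 luminal genes rose over the knockdown (median log2 fold change 2.10, camera adjusted p = 2.4e-06, adjusted p = 0.0367 with an estimated correlation), as did 17 of 18 adhesion genes with 1 not called (median log2 fold change 2.52, camera adjusted p = 5.4e-07, adjusted p = 0.00788 with an estimated correlation) and 27 of 32 estrogen-induced genes, with 2 lower and 3 not called (median log2 fold change 1.32, camera adjusted p = 3.2e-05, adjusted p = 0.234 with an estimated correlation). All 7 DNA replication genes fell (median log2 fold change -0.97, camera adjusted p = 1.1e-04, adjusted p = 0.0652 with an estimated correlation), and 6 of 8 G2/M genes fell with 2 not called (median log2 fold change -0.53, camera adjusted p = 0.00770, adjusted p = 0.254 with an estimated correlation). Mesenchymal genes were mixed: 10 of 17 fell, 2 rose and 5 were not called (median log2 fold change -0.36, camera adjusted p = 0.0642), and FN1 was at 78.2 ± 2.89 FPKM against 83.2 ± 2.61 FPKM in the knockdown (log2 fold change -0.09, SE 0.09, adjusted p = 0.385). Among markers of other cell types, CD68 fell (log2 fold change -0.43). Of 4 endothelial markers, CDH5 and TIE1 rose (1.45 and 0.72) and ROBO4 and ESAM fell (median log2 fold change 0.12, camera adjusted p = 0.923). Of 3 fibroblast markers, ACTA2 and PDGFRB rose (1.28 and 0.85) and COL1A1 was not called (median log2 fold change 0.85, camera adjusted p = 0.258; 3 higher adjusted over the list alone). The largest rises after KDM1A were S100A7, GDF15, ABCG1 and S100P (log2 fold changes 4.43, 4.32, 4.24 and 4.22, adjusted p at most 7.8e-09). The largest falls were TOMM6, G0S2, COTL1, ESM1 and TFPI2 (-4.82, -2.07, -2.04, -1.96 and -1.94, adjusted p at most 0.00351). limma called 4937 genes, 3023 higher and 1914 lower, and the share higher went from 61.2% to 50.2% with median-of-ratios scaling.

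Of the 5840 genes changed by knockdown, 5690 (97.4%) were called in the opposite direction in the WT rescue against the knockdown, and 4559 (78.1%) in the E239K rescue. The product of the call rates gives 48.6% and 39.2%. In the E239K rescue, 66.5% of the genes that knockdown raised and 88.6% of those it lowered were reversed, where the call rates give 30.1% and 47.6%. With median-of-ratios scaling these were 81.5% and 79.8%, where the call rates give 39.3% and 39.5%, so the gap between directions depended on scaling. Both comparisons use the knockdown libraries with opposite sign, which alone can produce opposite changes. Simulations of unchanged groups sharing those libraries gave 0 reversed genes in each of 20 draws. With unchanged groups hardly any gene is called, so this 0 follows from the setting. It does not measure what the shared libraries add to the shares reversed. Across genes, the knockdown and rescue log2 fold changes had r = -0.93 for WT and -0.86 for E239K, against -0.50 in the simulations, with covariances of -2.09 and -0.91 against -0.013. With 3 knockdown libraries, each comparison could not be given 2 of its own, and a split into 1 and 2 was not tried. The genes listed were mostly at least 2-fold apart between the WT rescue and the knockdown (91.5%), which raises the share reversed wherever control lies between these groups.

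The central question was how the E239K form differed from wild type, at KDM1A levels of 267 ± 27.6 and 243 ± 25.6 FPKM. ESR1 in the E239K rescue was 5.18-fold lower than in the WT rescue (log2 fold change -2.03, SE 0.12, adjusted p = 1.7e-08). Of 19 luminal genes, 17 were lower and 2 were not called (median log2 fold change -1.30, camera adjusted p = 1.2e-05, adjusted p = 0.0443 with an estimated correlation), with GATA3 3.81-fold, FOXA1 2.70-fold, TFAP2C 4.93-fold and the epithelial factor GRHL2 3.60-fold lower. Of 32 estrogen-induced genes, 25 were lower, 3 higher and 4 not called (median log2 fold change -0.99, camera adjusted p = 1.7e-05, adjusted p = 0.196 with an estimated correlation). CXCL12 was 2.10 ± 0.285 against 48.1 ± 10.4 FPKM (log2 fold change -3.97, SE 0.14, adjusted p = 2.0e-10) and RET was 4.40-fold lower. IGFBP4 and FHL2 were higher (11.2-fold and 9.25-fold). Of 18 adhesion genes, 17 were lower and 1 higher (median log2 fold change -1.08, camera adjusted p = 2.8e-05, adjusted p = 0.0265 with an estimated correlation), with CDH1 2.75-fold, CLDN3 3.11-fold, PKP3 2.46-fold and DSP 2.17-fold lower.

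Most mesenchymal and invasion genes tested were higher in the E239K rescue than in the WT rescue. Of 17 mesenchymal genes, 15 were higher, 1 lower and 1 not called (median log2 fold change 2.35, camera adjusted p = 0.00173, adjusted p = 0.306 with an estimated correlation). FN1 was 78.2 ± 2.89 against 8.34 ± 1.30 FPKM (log2 fold change 3.09, SE 0.09, adjusted p = 8.6e-11), TNC 40.9 ± 0.180 against 1.28 ± 0.760 FPKM, SNAI2 5.02 ± 0.191 against 0.117 ± 0.0901 FPKM and the cadherin CDH11 3.19 ± 0.0636 against 0.162 ± 0.0822 FPKM. Of 20 matrix and invasion genes, 15 were higher, 2 lower and 3 not called (median log2 fold change 1.66, camera adjusted p = 0.0169, adjusted p = 0.346 with an estimated correlation), including the membrane protease MMP14 (26.6-fold), the fibronectin receptor subunit ITGA5 (9.29-fold), COL12A1 (63.4-fold) and the protease inhibitor TIMP3 (19.5-fold). Of 10 basal markers, 8 were higher and 2 lower (median log2 fold change 3.23, camera adjusted p = 0.0501, not past the threshold, and 0.0397 after median-of-ratios scaling), with EGFR 12.5-fold and LAMB3 15.1-fold higher. Among markers of other cell types, CD68 was 10.1-fold higher, all 4 endothelial markers were higher (median log2 fold change 2.15, camera adjusted p = 0.0451, adjusted p = 0.346 with an estimated correlation; 0.0708 to 0.0754 without any 1 of the E239K rescue replicates), and of 3 fibroblast markers PDGFRB was higher (log2 fold change 1.26) while ACTA2 and COL1A1 were not called (median log2 fold change 0.28, camera adjusted p = 0.614).

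**Figure D2:**
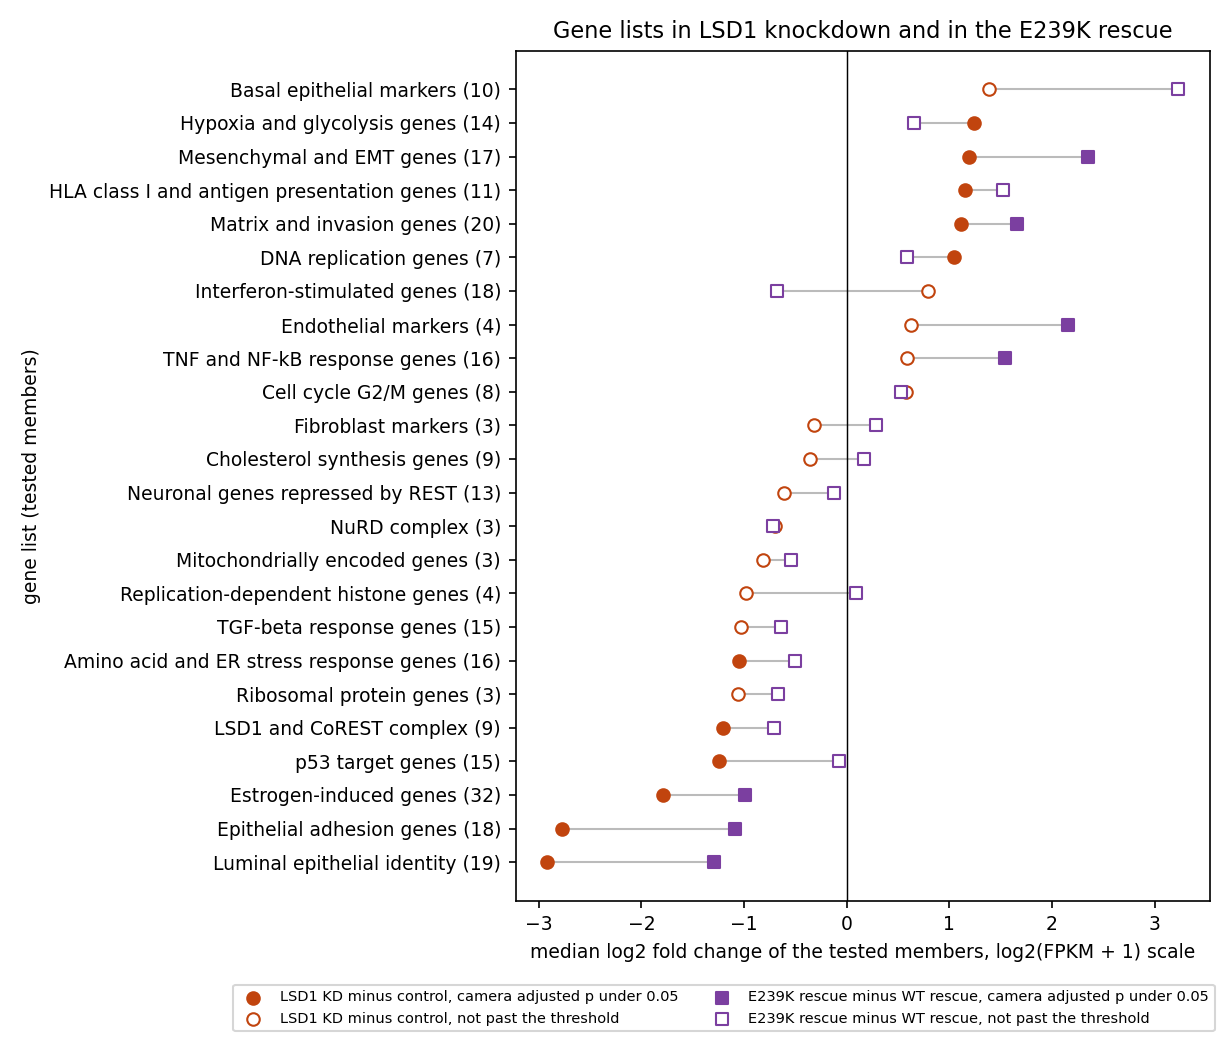
Median log2 fold change of the tested members of 24 gene lists (x axis, log2(FPKM + 1) scale), in LSD1 knockdown minus control (circles) and E239K rescue minus WT rescue (squares), filled where the camera adjusted p was under 0.05. Luminal, adhesion and estrogen-induced lists lay under 0 in both comparisons, and mesenchymal and matrix lists lay over 0 in both.

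Of 16 TNF and NF-kB response genes, 12 were higher, 2 lower and 2 not called in the E239K rescue against the WT rescue (median log2 fold change 1.54, camera adjusted p = 0.0352, adjusted p = 0.196 with an estimated correlation; 12 higher and 3 lower adjusted over the list alone). The call ended without E239K rescue replicate 2 or 3 (adjusted p = 0.0596 and 0.0584). FOSL1, an AP-1 subunit, was 69.2 ± 7.69 against 1.96 ± 0.587 FPKM, and TNFAIP2, KLF6 and the apoptosis inhibitor BIRC3 were 35.8-fold, 4.34-fold and 16.5-fold higher. Of 11 HLA and antigen presentation genes, 9 were higher and 2 lower (median log2 fold change 1.52, camera adjusted p = 0.0501, not past the threshold, and 0.0397 after median-of-ratios scaling), with PSMB8 at 19.7 ± 1.68 against 0.344 ± 0.242 FPKM. Interferon-stimulated genes split: 6 of 18 were higher, 11 lower and 1 not called (median log2 fold change -0.68, camera adjusted p = 0.0750). IFI6 was 12.9 ± 1.66 against 153 ± 32.4 FPKM and IFI27 and BST2 were lower (22.7-fold and 3.20-fold), while IFIT3 was 8.72-fold higher. Of 15 TGF-beta response genes, 9 were lower, 5 higher and 1 not called (median log2 fold change -0.64, camera adjusted p = 0.126, with a mean log2 fold change of 0.05 opposite in sign to the median), and TGFB2 was 21.8-fold higher.

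Of 7 DNA replication genes, 6 were higher and 1 was not called (median log2 fold change 0.59, camera adjusted p = 0.126), and of 8 G2/M genes 7 were higher and 1 was not called (median log2 fold change 0.53, camera adjusted p = 0.126). PCNA was 1.62-fold and CDC6 2.06-fold higher. Of 14 hypoxia genes, 9 were higher, 4 lower and 1 not called (median log2 fold change 0.65, camera adjusted p = 0.306), and of 9 cholesterol genes 4 were higher, 3 lower and 2 not called (median log2 fold change 0.17, camera adjusted p = 0.509), with PCSK9, which targets the LDL receptor for degradation, at 24.5 ± 0.567 against 0.0239 ± 0.0219 FPKM. Of 15 p53 targets, 4 were higher, 7 lower and 4 not called (median log2 fold change -0.08, camera adjusted p = 0.328). Of 16 amino acid and endoplasmic reticulum stress genes, 3 were higher, 10 lower and 3 not called (median log2 fold change -0.51, camera adjusted p = 0.0501, not past the threshold). Of 13 REST-repressed neuronal genes, 5 were higher, 6 lower and 2 not called (median log2 fold change -0.13, camera adjusted p = 0.322), with chromogranin A (CHGA) 11.5-fold lower. In the LSD1 and CoREST list, 6 of 9 were lower and 3 were not called (median log2 fold change -0.71, camera adjusted p = 0.0750, and 0.0397 after median-of-ratios scaling; 0.0478 without KDM1A, where adjusted p = 0.341 with an estimated correlation), with HMG20B 1.72-fold and GSE1 2.13-fold lower. All 3 NuRD, all 3 ribosomal and all 3 mitochondrial genes were lower, and of 4 histone genes 1 was higher, 1 lower and 2 not called (camera adjusted p = 0.0779, 0.111, 0.121 and 0.767).

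The largest single-gene rises of the E239K rescue over the WT rescue were PTX3 (212 ± 34.4 against 1.92 ± 1.16 FPKM; log2 fold change 6.25, SE 0.23, adjusted p = 3.4e-10), the aldose reductase AKR1B1 (141 ± 11.3 against 1.46 ± 0.766 FPKM; log2 fold change 5.90, SE 0.19, adjusted p = 1.3e-10), ANKRD1, a target of YAP signaling (269.5 ± 18.5 against 4.57 ± 2.97 FPKM), LDHB, NT5E, the receptor kinase AXL (196 ± 27.9 against 5.65 ± 3.09 FPKM), COL13A1, the membrane linker moesin (MSN), SRGN and the plasminogen activator PLAT. The largest falls after CXCL12 were UPK3BL1, NPY1R, SAMD11, the GDNF receptor GFRA1, IFI6, TMEM150C, PREX1, PKIB and TFF3 (log2 fold changes from -3.62 to -2.60). For UPK3BL1 (SE 1.22, adjusted p = 0.0164) the call ended without WT rescue replicate 2 (adjusted p = 0.0533) or replicate 3 (0.0502). limma called 5561 genes, 3108 higher and 2453 lower. Of these, 2354 were also at least 2-fold on the log2(FPKM + 1) scale (1722 higher and 632 lower). The share higher among all called genes went from 55.9% to 50.6% with median-of-ratios scaling. The median log2 fold change of 0.22 went to 0.05 with median-of-ratios scaling. UPK3BL1, LDHB, PKIB and TMEM150C share exon bases with another gene on the same strand (1156, 997, 454 and 128 bases), so their FPKM cannot be assigned to them alone.

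The comparison of knockdown with control and that of E239K rescue with WT rescue use no library in common. Of 5150 genes called in both, 5002 (97.1%) had the same direction and 148 the opposite. Across genes the log2 fold changes had r = 0.80 and rho = 0.83 (genes are not independent replicates). A high share follows from the listing of genes, since 91.5% of those listed differed at least 2-fold between the WT rescue and the knockdown, and control and E239K rescue mostly lay between these groups. In 20 simulated draws with the E239K rescue set to the control means, 91.4% to 92.1% of the genes called in both had the same direction, with r = 0.59 to 0.60. The share therefore does not measure how alike the changes were. PTX3, AXL, FN1 and FOSL1 were higher and GATA3, CDH1, GREB1 and CXCL12 lower in both. TOMM6, with a log2 fold change of 5.11 in the knockdown, was not past the threshold between the rescues (log2 fold change 0.29, SE 0.15, adjusted p = 0.0977).

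**Figure D3:**
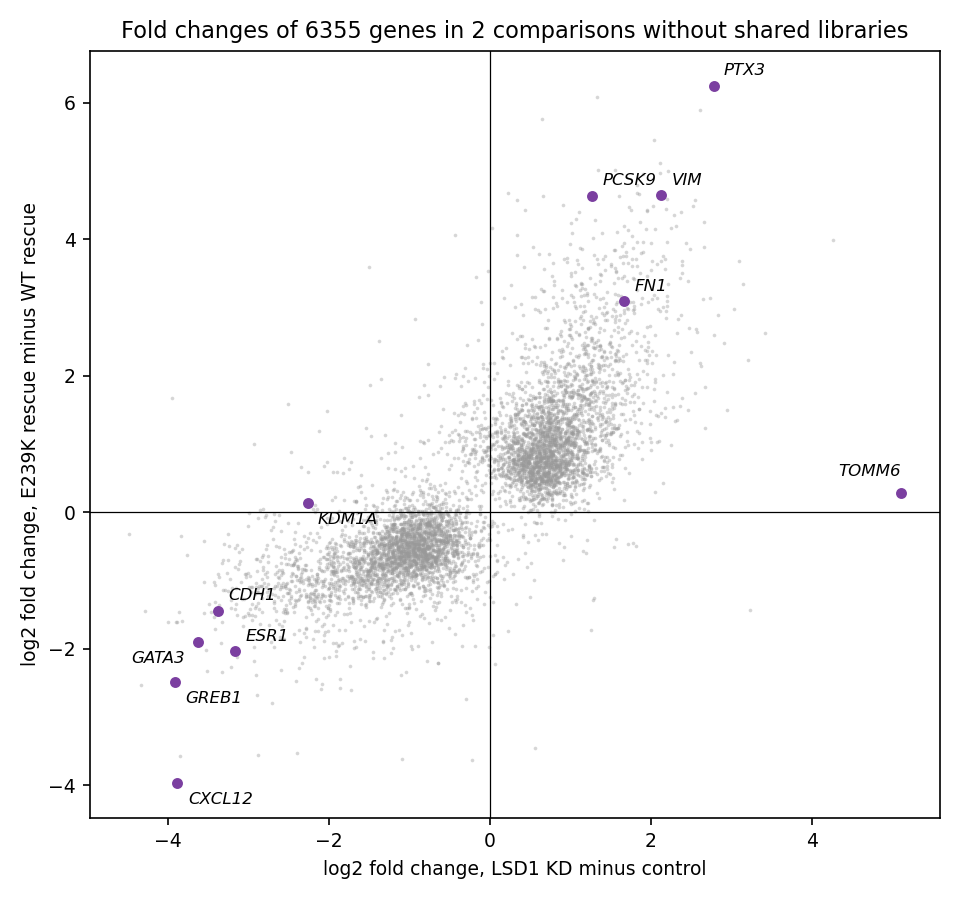
Log2 fold change of each of the 6355 tested genes in LSD1 knockdown minus control (x axis) and in E239K rescue minus WT rescue (y axis), both from log2(FPKM + 1), with 11 genes labelled. Most genes lie in the quadrants where both changes have the same sign (r = 0.80 across genes, against 0.59 to 0.60 in simulations with the E239K rescue set to the control means).

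The last comparisons asked what still differed from control cells after each rescue. In the WT rescue, ESR1 was 15.4 ± 2.56 against 12.8 ± 0.655 FPKM, not past the threshold (log2 fold change 0.24, SE 0.12, adjusted p = 0.0932). It passed with median-of-ratios or upper-quartile scaling (0.46 and 0.39) and without WT rescue replicate 3 (0.37). Epithelial adhesion genes were above control in 15 of 18, with 1 lower and 2 not called (median log2 fold change 0.63, camera adjusted p = 2.0e-06, adjusted p = 0.0123 with an estimated correlation), luminal genes in 12 of 19 with 7 not called (median log2 fold change 0.51, camera adjusted p = 2.0e-05, adjusted p = 0.0680 with an estimated correlation) and estrogen-induced genes in 23 of 32, with 3 lower and 6 not called (median log2 fold change 0.62, camera adjusted p = 2.0e-06, adjusted p = 0.198 with an estimated correlation; 24 higher adjusted over the list alone). Mesenchymal genes were under control in 14 of 17, with 2 higher and 1 not called (median log2 fold change -1.70, camera adjusted p = 0.00510, adjusted p = 0.332 with an estimated correlation). Among markers of other cell types, CD68 was 3.30-fold under control and all 4 endothelial markers were under control (median log2 fold change -1.83, camera adjusted p = 0.0489, adjusted p = 0.332 with an estimated correlation). Of 3 fibroblast markers, PDGFRB was lower (-0.55), ACTA2 higher (1.11) and COL1A1 not called (median log2 fold change -0.15, camera adjusted p = 0.791). Interferon-stimulated genes were above control in 15 of 18, with 2 lower and 1 not called (median log2 fold change 1.47, camera adjusted p = 6.5e-07, adjusted p = 0.293 with an estimated correlation), among them IFI6 at 153 ± 32.4 against 3.27 ± 0.510 FPKM. The largest rises were IFI6, GPNMB, KRT16, FOS and ISG15 (log2 fold changes 5.16, 4.07, 3.38, 3.30 and 2.85, adjusted p at most 2.4e-07). The largest falls were ANKRD1, LDHB, IL11, MT1E and AKR1B1 (-5.29, -4.53, -4.44, -4.20 and -4.15, adjusted p at most 2.8e-07). limma called 4479 genes, 1631 higher and 2848 lower, and the share higher went from 36.4% to 48.5% with median-of-ratios scaling. Of the genes changed by knockdown, 3836 were on the opposite side of control in the WT rescue, 264 on the same side and 1740 not called, where the call rates give 2033 opposite and 2083 on the same side.

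In the E239K rescue, ESR1 stayed 4.29-fold under control (log2 fold change -1.79, SE 0.12, adjusted p = 3.9e-07). Luminal genes were under control in 16 of 19, with 1 higher and 2 not called (median log2 fold change -0.65, camera adjusted p = 2.4e-05, adjusted p = 0.0501 with an estimated correlation), and estrogen-induced genes in 20 of 32, with 7 higher and 5 not called (median log2 fold change -0.53, camera adjusted p = 0.00130, adjusted p = 0.217 with an estimated correlation). Adhesion genes were under control in 10 of 18, with 2 higher and 6 not called (median log2 fold change -0.40, camera adjusted p = 0.0169, adjusted p = 0.123 with an estimated correlation; 3 higher adjusted over the list alone). Mesenchymal genes were above control in 12 of 17, with 2 lower and 3 not called (median log2 fold change 0.71, camera adjusted p = 0.00920, adjusted p = 0.260 with an estimated correlation), and matrix genes in 17 of 20 with 3 not called (median log2 fold change 1.24, camera adjusted p = 2.4e-05, adjusted p = 0.147 with an estimated correlation), such as ITGA5, LOXL2 and MMP1 (log2 fold changes 1.84, 1.41 and 1.37). All 10 basal markers (median log2 fold change 1.03, camera adjusted p = 4.4e-04, adjusted p = 0.147 with an estimated correlation) and all 11 HLA and antigen presentation genes (median log2 fold change 0.92, camera adjusted p = 1.4e-04, adjusted p = 0.0501 with an estimated correlation) were above control. Markers of other cell types moved beside them. CD68 was 3.06-fold above control. Of 4 endothelial markers, CDH5 (2.11 ± 0.0912 against 0.229 ± 0.0405 FPKM), ROBO4 and ESAM were higher and TIE1 lower (median log2 fold change 0.90, camera adjusted p = 0.186, not past the threshold). Of 3 fibroblast markers, PDGFRB (1.45 ± 0.130 against 0.504 ± 0.107 FPKM) and ACTA2 were higher and COL1A1 was not called (median log2 fold change 0.70, camera adjusted p = 0.172, not past the threshold). The largest rises were S100A7, SERPINA3, S100A9, KRT16 and PCSK9 (5.39, 4.11, 4.02, 3.93 and 3.02, adjusted p at most 1.8e-06). The largest falls were CXCL12, PREX1, CCN5, SAMD11 and ID2 (-2.45, -2.31, -2.28, -2.25 and -2.13, adjusted p at most 0.00353). limma called 3979 genes, 2235 higher and 1744 lower. Of the genes changed by knockdown, 3481 were on the same side of control in the E239K rescue, 318 on the opposite side and 2041 not called, where the call rates give 1818 and 1838. Each pair of comparisons shares the control libraries, which alone can put genes on the same side. In 20 simulated draws with each rescue set to the control means, 0 genes were called on the same side and 0 on the opposite side. Such a rescue has hardly any gene to call against control, so both counts follow from the setting. They do not measure what the shared control libraries add.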

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

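In this part, the tests of the mixtures, of graded regulation, of KDM1A, of CASP3 and of single list medians, and all counts and shares under other scalings, were chosen after the result was seen. The test of the gap between list medians and the regroupings of libraries were set beforehand.

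For 14 named genes the rescues moved in opposite directions from the knockdown, lower with wild-type LSD1 and higher with E239K. A called difference between E239K and WT rescue was part of the choice of these genes, so it is no separate support. In matrix and basal lists the genes were TIMP3, LAMC2, ITGA5, LOXL2 and MMP1 (log2 fold changes of E239K against WT rescue 3.865, 3.12, 2.934, 1.785 and 1.334). In signaling lists they were TGFB2, BIRC3, IL1B and TNFRSF10B (3.236, 2.442, 1.642 and 1.277). The others were PCSK9 and LDLR (4.64 and 1.491), HLA-A (1.842), TIE1 (1.423) and PDGFRB (1.258). Among all tested genes, 242 were lower in the WT rescue and higher in the E239K rescue than in the knockdown, and 12 the reverse, against 4599 called in the same direction in both. These tallies depended on scaling: 107 and 31 with median-of-ratios scaling and 165 and 17 with upper-quartile scaling. The higher expression in E239K than in WT rescue was called for all 14 named genes with either scaling, which largely follows from how they were chosen. The opposite directions from the knockdown were called for 9 with median-of-ratios and 10 with upper-quartile scaling. BIRC3, TGFB2, TNFRSF10B, LOXL2 and HLA-A lost their rise over the knockdown with median-of-ratios scaling (0.04, 0.08, 0.06, 0.08 and 0.11), and of these TGFB2 kept it with upper-quartile scaling (0.22).

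The E239K rescue libraries lay between the knockdown and WT rescue libraries. On the log2(FPKM + 1) scale, a weighted mean of those groups came within 1.5-fold of the E239K rescue mean for 86.2% of genes. A mixture of cells like those of the 2 other groups may contribute. It predicts the same knockdown-like share from genes high in either group, and the shares were 0.614 from 545 genes high in the knockdown and 0.635 from 497 genes high in the WT rescue (difference -0.02053, 95% bootstrap interval -0.051 to 0.003). On the values as listed that interval lay within the bound of 0.1, as a mixture predicts. With median-of-ratios scaling the difference was -0.224 and with upper-quartile scaling -0.147, both past that bound. Such factors differ between groups (median-of-ratios 0.882 for knockdown replicate 1 and 1.07 for E239K rescue replicate 1). That alone moves the 2 shares apart, also for a mixture, so the rescaled differences cannot count against one. The right scaling of a selected set of genes is not known, so the shares decide neither for nor against a mixture. Against a mixture of exactly the 2 group means as the whole account, 188 genes lay at least 1.5-fold outside their range. On the same log2(FPKM + 1) scale, 2 sets of 20 simulated mixtures gave at most 3 and at most 4. With those scalings 122 and 133 genes lay outside, against at most 4 and at most 3. The simulations used the measured means of the 2 groups. Cells that only resemble those groups could also place genes outside, and that was not simulated. Movement of each gene by the same part of its log range is argued against by a gap of 0.4276 between the 2 gene sets (0.267 and 0.326 with those scalings). This gap also moves with the scaling, so the argument covers only the scalings tried. Lower KDM1A RNA in the mutant cells is excluded by its log2 fold change of 0.1354, but LSD1 protein was not measured. A partial loss of LSD1 function through E239K was not tested. It cannot be told apart from a partial mixture, or from a mixture of cells that only resemble the 2 groups.

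The control libraries also lay between the knockdown and WT rescue libraries. On the log2(FPKM + 1) scale, a weighted mean came within 1.5-fold for 88.2% of genes. The shares were 0.283 and 0.407 (difference -0.1239, interval -0.152 to -0.084), which straddles the bound of 0.1. They were apart by -0.280 and -0.207 with median-of-ratios and upper-quartile scaling, whose factors alone can move shares apart. A mixture and a regulated difference cannot be told apart. Equal movement on the log scale is argued against by a gap of 0.3675 (0.233 and 0.302 with those scalings), for the scalings tried only. KDM1A RNA above its control level, at 243 against 38.1 FPKM, may also separate WT rescue from control cells, and that was not tested.

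Mesenchymal genes were high and luminal genes low in the knockdown libraries, a gap of 4.11 between list medians against control. The gap was 4.084 after median-of-ratios scaling, which decides nothing, since a factor per library moves both lists alike. The single medians do move with such factors. These ran only from 0.881 to 1.08 in the knockdown and control libraries, too small a range to bring either median to 0. After that scaling the medians were -2.67 for luminal genes (95% bootstrap interval -2.96 to -1.94) and 1.42 for mesenchymal genes (0.712 to 1.94). With factors that small the outcome was fixed in advance, so it argues only against scaling of that size as the cause of either part. The right scaling of a selected set of genes is not known, so a larger factor is not excluded for either part alone. Cells of another origin may be present: CASP3, of which MCF7 lacks a functional copy, was 16.9 ± 1.26 FPKM in the knockdown and 2.23 ± 0.458 FPKM in the WT rescue (log2 fold change 2.479), but control libraries also had 7.05 ± 0.335 FPKM and FPKM cannot show whether the transcript is intact, so this and a change of cell state cannot be told apart. The abundant mesenchymal transcript VIM stood at 461 ± 12.8 FPKM in the control libraries. A change of state caused by loss of LSD1, the difference named by the design, remains open and was not tested.

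For each comparison, 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. Splits other than the grouping studied mix 2 groups that differ in most tested genes. Few calls for them follow from that setting, so their counts do not measure how many calls arise by chance. The grouping studied was the 1 split in each with as many calls: 5840 against at most 0 for other splits in knockdown against control, 6176 against 0 in WT rescue against knockdown, 4937 against 1 in E239K rescue against knockdown, 5561 against 2 between the rescues, 4479 against 0 in WT rescue against control and 3979 against 0 in E239K rescue against control.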

How the results depend on the processing

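In this part, the filter of 5 FPKM, the pseudocount of 0.1 with the same filter and the restriction to Ensembl genes were chosen after the result was seen. Of 132 alternative values of the 8 gene counts, 119 stayed within 1.5 times the main count and 13 did not. For named genes, 10060 alternative values kept direction and call, 221 lost the call, 33 gained it and 1 changed sign. For gene lists, 1404 kept them, 73 lost the call, 95 gained it and 3 changed direction. Read depth is unknown, so its limit on low genes could not be set, and the count-based alternatives were not run for lack of counts.

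Requiring at least 2-fold gave 2803 genes in knockdown against control, 1296 in E239K rescue against knockdown, 2354 between the rescues, 1110 in WT rescue against control and 624 in E239K rescue against control, with 2611 knockdown genes reversed by WT and 1096 by E239K. A filter of 5 FPKM tested 3943 genes and called 3728, 3881, 3268, 3546 and 2514 in knockdown against control, WT rescue against knockdown, E239K rescue against knockdown, between the rescues and in E239K rescue against control, with 3669 knockdown genes reversed by WT. Both follow from their construction, which calls or tests fewer genes. MTA3 in E239K rescue against knockdown turned from 0.26 to -0.0217 with median-of-ratios scaling, which moved the median of all genes in that comparison from 0.26 to 0.05. fry gave the opposite direction to camera for HLA genes in E239K rescue against knockdown (adjusted p = 0.0227), and in WT rescue against control for TGF-beta genes (5.2e-04) and hypoxia genes (0.00462). fry compares a list with no change and camera with other genes, but the cause was not tested.

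With any 1 library left out, the counts were 5563 to 5680 in knockdown against control, 6001 to 6049 in WT rescue against knockdown, 4556 to 4721 in E239K rescue against knockdown, 5312 to 5497 between the rescues, 4120 to 4286 in WT rescue against control and 3533 to 3680 in E239K rescue against control. Genes reversed were 5424 to 5650 for WT and 4188 to 4473 for E239K. Replicate number as a block gave 5547 genes between the rescues against 5561. An estimated correlation ended 48 list calls and left 96 of 144 list results on the same side of the threshold.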

Other observations

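In this part FGB, AGR2, SAT1 and the set of genes highest in the E239K rescue were chosen after their values were seen, and no test was run for this part alone. The E239K rescue had a set of genes above all 3 other groups. On the log2(FPKM + 1) scale, 137 genes were at least 1.5-fold above each of them and 1 was below, each called in 3 comparisons. With median-of-ratios scaling 87 were above and 6 below, and with upper-quartile scaling 99 and 3. S100A7 was 64.0 ± 3.90 FPKM against 0.557 ± 0.162 in control, 2.06 ± 0.639 in knockdown and 4.14 ± 0.972 in WT rescue libraries. S100A9 was 34.4 ± 5.56 FPKM against 3.02 ± 0.395 in the knockdown, where it was highest among the other groups. FGB, a fibrinogen chain, was 15.1 ± 0.619 FPKM against 0.475 ± 0.0882 in the WT rescue, and the acute phase inhibitor SERPINA3 was 36.5 ± 17 FPKM against 6.39 ± 2.60. AGR2, a disulfide isomerase of secretory cells, was 41.7 ± 2.71 FPKM against 8.73 ± 2.64 in the WT rescue, and SAT1, which catabolises polyamines, was 110.3 ± 0.729 FPKM against 42.1 ± 6.11. SERPINA3 shares 1592 exon bases with another gene on the same strand.

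Most sterol and inflammatory genes tested were also above control in the E239K rescue. Of 9 cholesterol synthesis genes, 8 were higher and 1 was not called (median log2 fold change 0.66, camera adjusted p = 0.00158, adjusted p = 0.211 with an estimated correlation). PCSK9 was 24.5 ± 0.567 FPKM against 2.16 ± 0.221 in control, and LDLR, the LDL receptor, was 98.1 ± 3.15 FPKM against 38.5 ± 0.483. Of 16 TNF and NF-kB response genes, 13 were higher, 2 lower and 1 not called (median log2 fold change 0.90, camera adjusted p = 0.00117, adjusted p = 0.0501 with an estimated correlation; 13 higher and 3 lower adjusted over the list alone). The adhesion receptor ICAM1 was 7.72 ± 0.615 FPKM against 2.73 ± 0.157 and IL1B was 2.19 ± 0.227 FPKM against 0.00959 ± 0.0166. Of 18 interferon-stimulated genes, 15 were higher, 1 lower and 2 not called (median log2 fold change 1.06, camera adjusted p = 2.5e-04, adjusted p = 0.251 with an estimated correlation). Of 15 p53 targets, 8 were higher, 3 lower and 4 not called (median log2 fold change 0.36, camera adjusted p = 0.205), with the cell cycle inhibitor CDKN1A at 111 ± 5.92 FPKM against 31.7 ± 1.03.

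The number of listed genes at 0 FPKM averaged 43.0 in control, 175 in knockdown, 287 in WT rescue and 16.7 in E239K rescue libraries.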
